A study of Homo sapiens with 6 samples.

How the data were processed

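RNA-seq of 6 libraries from OCI-AML3, an established human acute myeloid leukaemia cell line, was analysed. 3 libraries carried an empty lentiviral vector, per the titles and genotype labels, and 3 overexpressed SLC2A3, which encodes the glucose transporter GLUT3. Per the labels, every culture received 250 µM vitamin C and libraries were made from Trizol-extracted RNA with a NEBNext Ultra II Directional kit. The labels state neither how messenger RNA was selected nor whether counting used strand. The submitters' processing notes name BWA, TopHat2 and the genome build hg38 without roles or versions, and the gene annotation is not given in the sources used here.

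Each file lists 60660 gene IDs with 1 value. The deposited values are a normalised signal, gene read counts divided by 1 factor per library. This was found from the values: 100% of them were whole multiples of the smallest positive value in their library, within a tolerance of 0.001 reads. The factors, 0.936 to 1.08, equalled DESeq2's median-of-ratios size factors computed on the recovered reads. Recovered reads summed to between 31054462 and 35770556 per library. Of the IDs, 60597 matched a symbol in the gene name table or, failing that, GENCODE 29. Coordinates are from GENCODE 29 on GRCh38, 1-based, and may differ from the annotation the authors used.

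The plan fixed before the data were examined assumed raw counts and edgeR. It named limma-trend for files of RPKM, FPKM, TPM or CPM, and did not name counts divided by size factors. Limma-trend was chosen for these once the files were seen, although edgeR could be run on the recovered reads. log2(value + 1) was fitted with limma 3.58.1 in R 4.3.3 with group as the only term, for 28015 genes with a value of at least 1 in at least 3 libraries. P-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. Values are means ± SD of normalised read counts, and SE is the standard error of the log2 fold change. The labels do not say that replicates are separate cultures, so p-values measure only the spread between these samples, which may be technical. Intervals on read counts cover counting error only. A bound for a group without reads was set against 3 reads over the group. It takes the reads of the other group as exact, so it is not a 95% limit.

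35 gene lists, fixed before the data were examined, were tested against all other genes with camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation. They were also tested with fry, which asks whether list members shifted together in the same direction, without reference to other genes. A list whose members moved both ways can therefore fail it. Lists needed at least 5 tested members. Named genes followed a fixed rule: SLC2A3, then the 12 largest changes in each direction among genes past the threshold, with non-overlapping groups, a mean value of at least 5 in the higher group and a name that is not that of a pseudogene or noncoding RNA. That limit was the plan's for normalised values. Its limit for raw counts was higher and would have left out low-read genes such as ARC and H3-4. Up to 4 called members per list and SLC2A1, SLC2A14, SLC23A2, TET1, TET2 and TET3 were added. Any other gene is said to have been chosen after its values were seen.

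Replicates were compared by chi-square over genes with at least 10 reads in the pair. No pair agreed within sampling noise, with a chi-square per gene of 3.50 to 6.78, so all 6 libraries were kept. The same functions were tested on simulated counts for this comparison with 200 changed genes. Over 29772 simulated genes, limma-trend recovered 52% of 100 genes changed 1.5-fold and 72% of 100 changed 2-fold, and 1 of its 125 calls was false. The 1 shifted list, of 25 genes shifted by a log2 change of 0.2, was found and 0 of 30 unshifted lists were called. Genes varied independently in that simulation. Gene changes under 1.5-fold and smaller list shifts were not simulated, so recovery at those sizes was not measured.

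Alternatives covered edgeR 4.0.16 with 4 scalings, DESeq2 1.42.0 and limma-voom on the recovered reads, other filters and pseudocounts, other scalings, a replicate block, and each library left out. The count tests on recovered reads change the test as well as the choice they were planned for. edgeR's quasi-likelihood test with TMM factors called 285 genes higher and 328 lower among 18630 tested.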

Results

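The data are gene-level normalised read counts of OCI-AML3 cells grown with 250 µM vitamin C, 3 libraries with an empty vector and 3 with SLC2A3 overexpression. Library depth was 32581096, 33162128 and 33073173 recovered reads in the empty vector group and 35770556, 34590069 and 31054462 in the SLC2A3 group. The comparison asks how raised expression of the glucose transporter GLUT3, whose family also carries oxidised vitamin C, alters gene expression in vitamin C-treated leukaemia cells. No group without vitamin C is analysed here, so an effect of the vitamin is not separated from one of the transporter.

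SLC2A3 (ENSG00000059804.16, chromosome 12, 7919230 to 7936275, GRCh38) was 3.25-fold higher in the SLC2A3 group, at 3942 ± 196 against 1211 ± 40.2 normalised reads (SD, n = 3 per group). Its log2 fold change was 1.70 (SE 0.057, limma adjusted p = 7.95e-18). The values were 1194, 1183 and 1257 in the empty vector libraries and 4056, 3716 and 4054 in the SLC2A3 libraries. Gene counts do not separate vector-derived from endogenous transcripts. SLC2A14, a close relative of SLC2A3 with which reads could be shared, stood at 9.72 ± 2.02 against 8.99 ± 3.84.

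Most other changes were small. The stress-inducible chaperone HSPA6 rose 6.28-fold, from 120 ± 16.7 to 759 ± 73.0 normalised reads (n = 3, limma adjusted p = 9.14e-15), and its relative HSPA1B rose 2.57-fold. TXNIP, an inhibitor of glucose uptake, fell 1.79-fold, from 3974 ± 73.6 to 2214 ± 41.6 normalised reads (n = 3, limma adjusted p = 7.38e-12). AGXT, a glyoxylate-detoxifying aminotransferase, fell 2.07-fold, and FOS, an immediate early transcription factor, fell 1.56-fold. In all, 194 genes were higher and 224 lower of 28015 tested, and 22 changed over 2-fold, 16 up and 6 down. Of the 418 called genes, 371 changed less than 1.5-fold, and the median size of their log2 change was 0.265. The groups did not overlap for 416 of them. Among all tested genes 16.3% did not overlap, against 10% by chance. The call counts depended on single libraries. Without SLC2A3 overexpression replicate 3, 100 genes were higher and 88 lower, and without empty vector replicate 3, 121 and 100. Without empty vector replicate 1, 132 genes were higher and 132 lower, and without SLC2A3 overexpression replicate 2, 157 and 140.

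**Figure D1:**
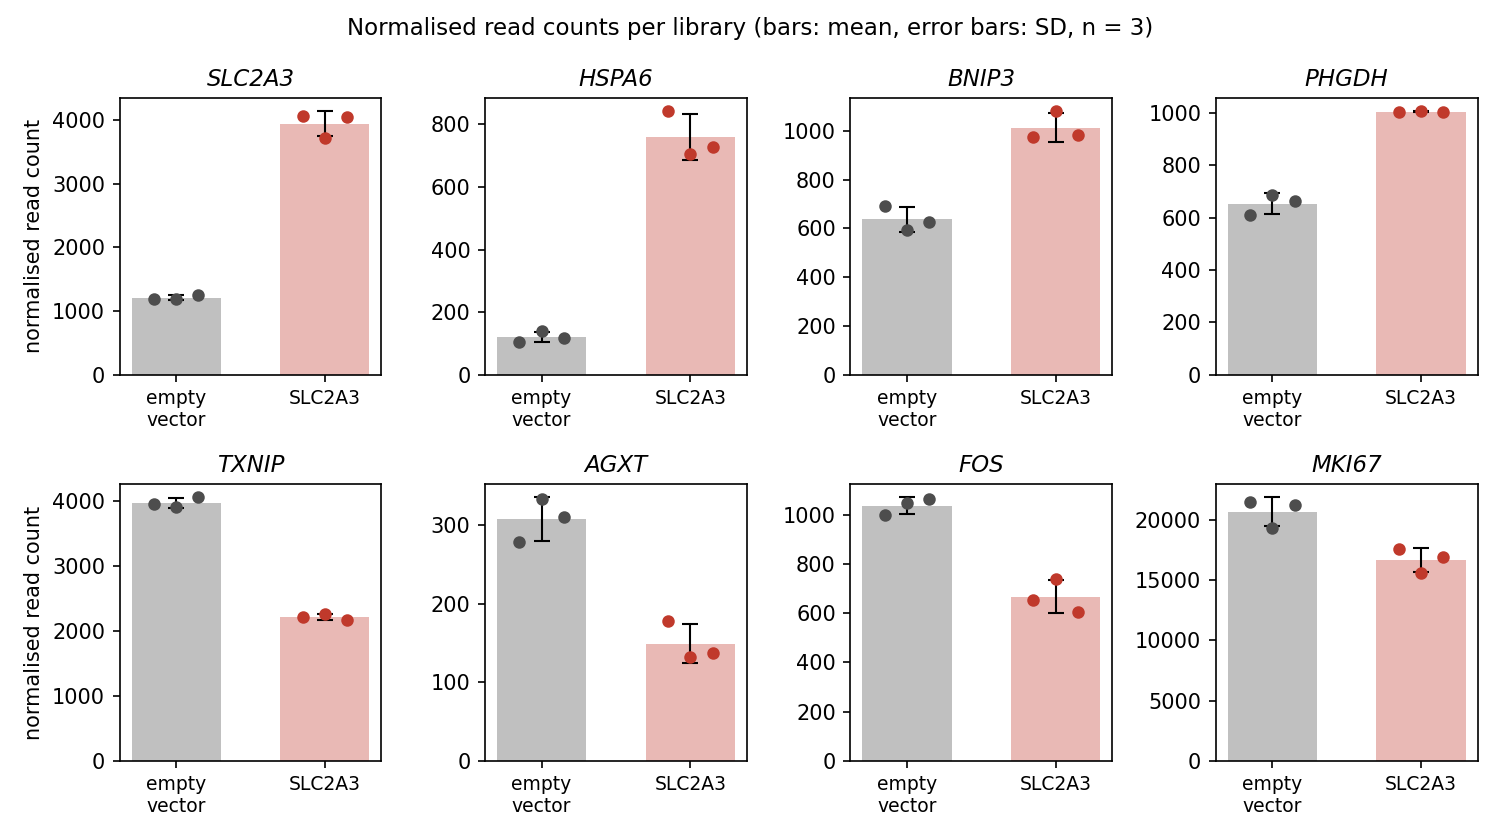
Normalised read counts (vertical axes, linear from 0) of 8 genes in the empty vector (grey) and SLC2A3 (red) libraries. Points are libraries, bars means and error bars SD (n = 3); for SLC2A3 the 3 overexpression libraries lie at 3716 to 4056 and the empty vector libraries at 1183 to 1257.

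Among the other genes with the largest gains, STC1, a secreted glycoprotein, rose 2.48-fold, RGS2, a regulator of G-protein signalling, 2.22-fold, DDIT4, an inhibitor of mTORC1, 2.21-fold, and ID1, an inhibitor of basic helix-loop-helix factors, 2.13-fold. The histone genes H2AC16, H3C2, H3C13 and H1-5 were also among them. The libraries with the most H1-5 reads in each group were also those with the most of the noncoding RNA RN7SL1, a gene chosen after its values were seen. In both groups this was replicate 2. ARC had 0 reads in the empty vector group and 24 in the SLC2A3 group, 7.8-fold higher if set against 3 reads. CNKSR2 rose from 1.33 ± 2.31 to 12.7 ± 5.99 normalised reads (adjusted p = 0.041) and was not called when any 1 of 5 libraries was left out, empty vector replicate 3 being the exception. At the other end, H3-4 had 24 reads in the empty vector group and 0 in the SLC2A3 group. Set against 3 reads, H3-4 was 8.2-fold lower. MTRNR2L8, which resembles mitochondrial ribosomal RNA and may share its reads, had 36 against 2 reads, a ratio of 18.5 (95% counting interval 4.75 to 158). MYADML2 had 28 against 2 reads, a ratio of 14.4 (3.62 to 124). SMIM10L2A, SPTBN5, TREML1, BICDL1, APC2 and C3orf52 completed the 12 largest decreases, with log2 fold changes of -2.43, -1.14, -0.76, -0.64, -0.56 and -0.50.

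Of the 35 gene lists, 16 passed camera with the preset correlation, 10 higher and 6 lower, and 8 held with an estimated correlation. The preset count may overstate the evidence. The 9 other ways of dividing the 6 libraries into groups of 3 passed 3 to 10 lists with the preset correlation and 0 with an estimated correlation. Each of these divisions mixes the empty vector and SLC2A3 libraries, so part of any group difference remains and the rest widens their spread. They are therefore no chance baseline for either count. Of the 8 lists that held, 7 are described first, and 1, lower in the SLC2A3 group, is left out of this text and of the figure.

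**Figure D2:**
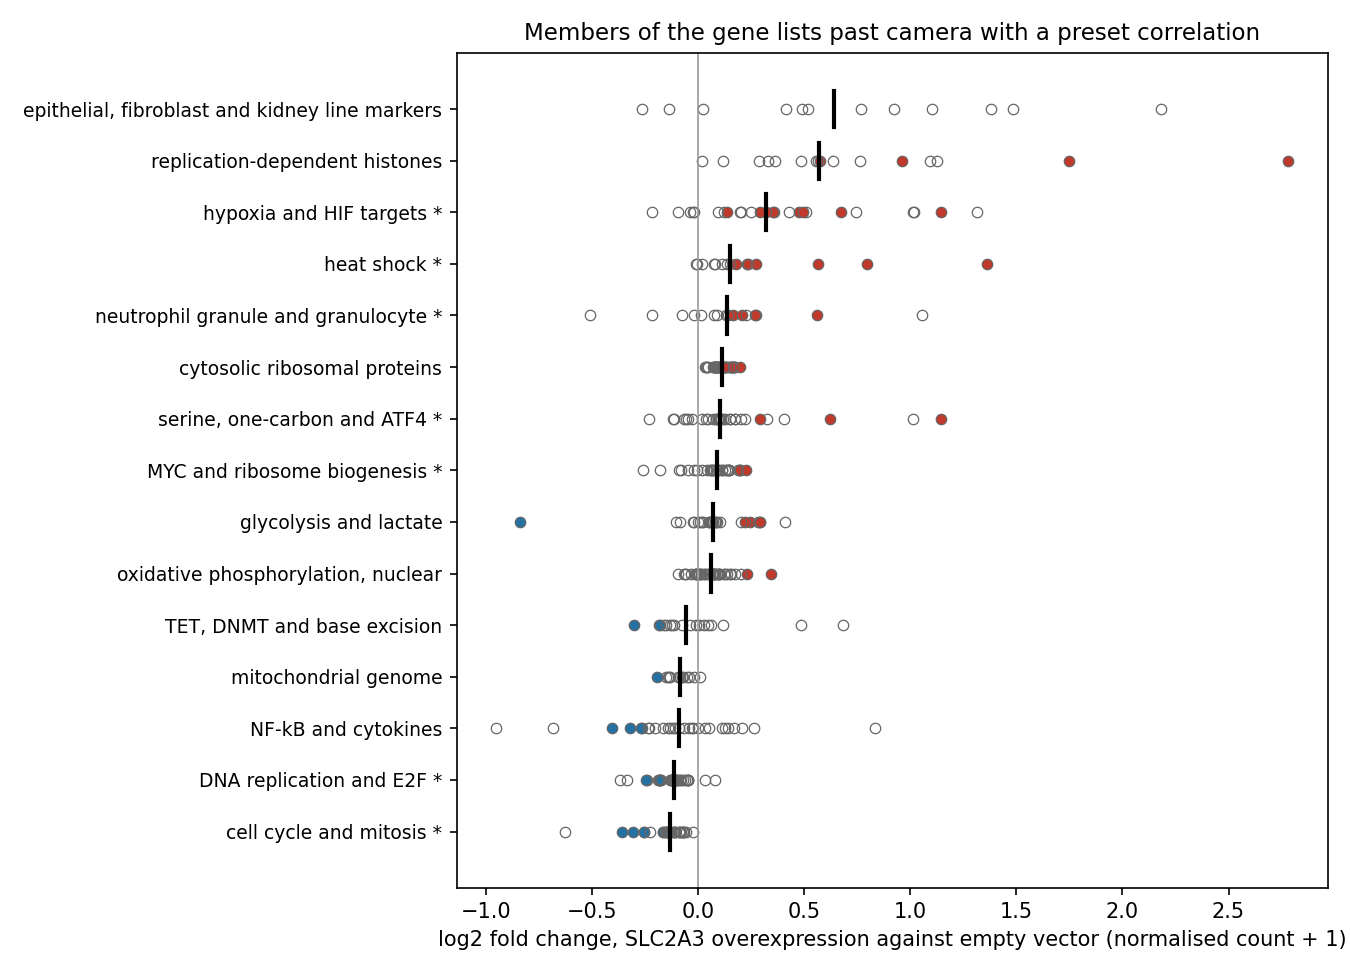
Log2 fold changes of list members (horizontal axis, SLC2A3 overexpression against empty vector) for 15 of the 16 lists past camera with a preset correlation. Filled points passed the gene-level threshold (red higher, blue lower), open points did not, black ticks are list medians, and asterisks mark the 7 of these that held with an estimated correlation.

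Of 25 tested hypoxia and HIF target genes, 8 rose and 17 did not pass (list median log2 change 0.32, adjusted p = 0.0201 with an estimated correlation). The mitophagy receptor BNIP3 rose 1.59-fold, the collagen prolyl hydroxylase P4HA1 1.39-fold and the adenylate kinase AK4 1.41-fold. With p-values adjusted over each list alone, counts were higher: 13 rose here, 10 in the heat shock list, 6 in the serine list, 12 in the MYC list with 1 lower, and 6 in the neutrophil list, and 12 fell in the mitosis list and 12 in the replication list.

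Of 15 heat shock genes, 6 rose (median 0.15, adjusted p = 0.0142 with an estimated correlation). HSPA1A rose 1.74-fold, the co-chaperone DNAJB1 1.48-fold and the abundant chaperone HSP90AA1 1.17-fold. HSPA1A and HSPA1B are near-identical copies, so the division of reads between them is uncertain.

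Of 32 serine, one-carbon and ATF4 genes, 3 rose (median 0.10, adjusted p = 0.0201 with an estimated correlation). PHGDH, the first enzyme of serine synthesis, rose 1.54-fold and SLC7A11, the cystine transporter, 1.22-fold, and the third was DDIT4, which the hypoxia list also holds. Of 30 MYC and ribosome biogenesis genes, 3 rose, the nucleolar factors PES1, BOP1 and FBL, by 1.17-fold, 1.15-fold and 1.14-fold (median 0.09, adjusted p = 0.0201 with an estimated correlation). Of 16 tested neutrophil granule and granulocyte genes, 4 rose (median 0.14, adjusted p = 0.0323 with an estimated correlation). However, this list did not pass fry (adjusted p = 0.0672) and its median was 0.079 without empty vector replicate 2. The granule protease PRTN3 rose 1.47-fold, RNASE2 1.20-fold, MMP9 1.15-fold and CTSG 1.12-fold.

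Of 31 mitosis genes, 5 fell (median -0.13, adjusted p = 0.0317 with an estimated correlation), among them the proliferation marker MKI67 with a log2 change of -0.31, KIF20A with -0.36 and PLK1 with -0.26. Of 33 DNA replication and E2F genes, TK1 and MCM5 fell, with log2 changes of -0.25 and -0.18 (list median -0.12, adjusted p = 0.0142 with an estimated correlation).

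The other 8 lists passed with the preset correlation but not with an estimated correlation. Among them only the cytosolic ribosomal protein and NF-kB lists passed fry (adjusted p = 0.0406 and 0.0211). Adjusted over each list alone, 38 ribosomal protein genes, 6 histone genes and 3 nuclear oxidative phosphorylation genes rose, 6 glycolysis genes rose and 1 fell, 5 mitochondrially encoded and 4 DNA methylation genes fell, and 3 NF-kB genes rose and 5 fell. Counts below are over all genes. Of 43 cytosolic ribosomal protein genes, 10 rose, RPS18 by 1.15-fold, with adjusted p = 0.0863 with an estimated correlation of 0.41. Of 16 replication-dependent histone genes, 4 rose (H1-2, H1-4, H1-5 and H3C2; adjusted p = 0.0863 with an estimated correlation), and the list median of 0.57 was 0.36 without SLC2A3 overexpression replicate 2. Of 26 glycolysis genes, LDHA, PFKFB4 and HK2 rose 1.16-fold, 1.22-fold and 1.18-fold and TXNIP fell (adjusted p = 0.0659 with an estimated correlation). COX5B and COX6C rose among 42 nuclear oxidative phosphorylation genes (adjusted p = 0.17), and MT-ND4L fell among 13 mitochondrially encoded genes (adjusted p = 0.232, both with an estimated correlation). TNF, TNFAIP3 and TNFAIP2 fell among 29 NF-kB and cytokine genes, with log2 changes of -0.41, -0.32 and -0.27 (adjusted p = 0.0863 with an estimated correlation). None of 12 epithelial, fibroblast and kidney line markers passed, most of them at low reads (adjusted p = 0.226 with an estimated correlation), and that list also did not pass with edgeR, DESeq2 or limma-voom when group was the only term. It also lost its call with no filter on low values, without SLC2A3 overexpression replicate 2, where its median of 0.64 was 0.28, and without both libraries highest in RN7SL1. It passed with edgeR once a replicate block was added (adjusted p = 0.0402).

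Vitamin C is a cofactor of the TET enzymes and other 2-oxoglutarate dioxygenases. Read counts give the transcript levels of these enzymes and do not measure their activity. TET1, TET2 and TET3 did not pass the test, with log2 changes of 0.49, -0.14 and -0.16 (adjusted p = 0.561, 0.621 and 0.145), although TET3 passed under 1 alternative, DESeq2 with its default filtering (adjusted p = 0.0334). Of 18 genes of DNA methylation and base excision, the maintenance factors UHRF1 and DNMT1 fell, with log2 changes of -0.31 and -0.19 (adjusted p = 0.222 for the list with an estimated correlation). SLC23A2, a sodium-coupled vitamin C transporter, had a log2 change of -0.02, and SLC2A1, which encodes GLUT1, 0.15 (adjusted p = 0.96 and 0.212). Once a trend with transcript length and GC content was removed, SLC2A1 passed narrowly, at 0.18 (adjusted p = 0.0495). SLC2A9, a urate transporter, was the only one of 13 tested transport genes past the threshold, with a log2 change of -0.30, and lost its call without any 1 of the 6 libraries.

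The remaining 19 lists, that of glucose and ascorbate transport included, did not pass. With the preset correlation, 3 of them passed under some of the 23 alternatives, antigen presentation under 5 (lowest adjusted p = 0.00452), immediate early genes under 5 (0.0118) and the BCL2 family under 2 (0.0392). SLC7A11 and TXN rose in the redox list, KLF4 and FCN1 rose in the monocyte list, SOX4 rose in the progenitor list, and FLT3 fell in the HOX and MEIS1 list. P4HA1 rose and KDM5C fell among the JmjC and other dioxygenases, HSP90B1 and MANF rose and ERN1 and CREB3L2 fell in the unfolded protein response list, and SCD rose in the cholesterol list and STEAP3 in the iron list. TAPBP fell in the antigen presentation list and the pro-apoptotic BCL2L11 in the BCL2 family list. The immediate early list held changes in both directions, with JUN 1.55-fold higher and FOS and EGR1 lower. The interferon list, with 39 tested members, the TCA cycle list, with 21, the pentose phosphate list, with 10, and the epithelial, erythroid, megakaryocyte, T and NK cell and B cell marker lists had 0 called members by limma. Among the 122 members of these lists, 17 had an unadjusted p under 0.05 by limma, against 3293 of all 28015 tested genes. edgeR and DESeq2 with its default filtering called 0 of the members. They could not call members that they filtered out, and DESeq2 gave no adjusted p under a mean of 413 normalised reads. Median, mean and test differed in sign for the transport, dioxygenase, HOX, BCL2, cholesterol and erythroid lists, none of which passed.

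Of the 83 called named genes other than SLC2A3, 42 lost their call when at least 1 library was left out, and 41 did not. Those that kept it include HSPA6, HSPA1A, DNAJB1, TXNIP, AGXT, FOS, JUN, BNIP3, P4HA1, AK4, LDHA, PHGDH, PRTN3, UHRF1, MKI67, KIF20A, TK1, PES1, RPS18, COX5B and TNF. Among those that lost it, ARC, SLC7A11, HK2, PFKFB4, DNMT1, PLK1, MCM5, BOP1, FBL, MMP9, TNFAIP3 and TNFAIP2 reached adjusted p of 0.0637 to 0.155 without 1 library, and CNKSR2 0.264. The low-read genes H2AC16, H3-4, MTRNR2L8, MYADML2 and SMIM10L2A, and SPTBN5, TREML1 and APC2, also lost theirs, as did TXN, KDM5C, FLT3, KLF4, FCN1, STEAP3, MT-ND4L, COX6C, BCL2L11, HSP90B1, MANF, ERN1 and CREB3L2. TXN and KDM5C were also not called once the length and GC trend was removed.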

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

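The other scalings of limma, the trend removal and the fit without both libraries highest in RN7SL1 were chosen after seeing the data. So were DESeq2 without independent filtering and, as an alternative, edgeR with TMM factors on recovered reads and group as the only term. The plan held that edgeR test as the main one for raw counts. The SLC2A3 log2 change stayed past the threshold in all alternatives run for it, at 1.68 to 1.74. Of 83 other called named genes, 40 passed under every alternative that gave them an adjusted p, and no called gene or list reversed. Over 2-fold, edgeR called 36 genes with TMM, relative log expression or total scaling and 34 with upper-quartile scaling. edgeR called 297 genes higher and 312 lower with relative log expression scaling and 303 higher and 265 lower with upper-quartile scaling. DESeq2 with its default filtering called 337 genes higher and 463 lower but 2 over 2-fold, since it gave no adjusted p under a mean of 413 normalised reads, where 19 of the 22 genes over 2-fold lie, all 19 with the same sign. Without that filtering it called 225 higher, 245 lower and 15 over 2-fold. Requiring at least 50 reads in 3 libraries gave 322 higher, 416 lower and 13 over 2-fold, with fewer genes tested. A pseudocount of 0.1 gave 140 higher and 144 lower. Removing the length and GC trend gave 293 higher and 266 lower, so the balance between directions (194 higher and 224 lower) turned under this alternative and under upper-quartile scaling; the cause was not tested. Leaving out 1 library gave 100 to 222 genes higher and 88 to 244 lower, with fewer samples, and the balance also turned without empty vector replicate 3 and without SLC2A3 overexpression replicate 2 or 3. Without both libraries highest in RN7SL1, 256 were higher and 260 lower. Lists past the threshold numbered 8 with an estimated correlation and 9 with fry. Over 12688 genes together, the replicate numbers did not pair the samples (correlations of -0.08, 0.01 and 0.00, and 0 samples closest to their own number). In both groups, however, replicate 2 was the library highest in RN7SL1, at 1812 and 6026 normalised reads. A link between equal numbers is therefore not excluded for single genes. A replicate block gave 167 genes higher, 196 lower, 26 over 2-fold, 16 lists and an SLC2A3 log2 change of 1.70. Low read numbers limit genes such as ARC, CNKSR2, H3-4, MTRNR2L8 and MYADML2, each of which lost its call under several alternatives.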

Other observations

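The tests of explanations below were chosen after the results were seen, except for the counts over other divisions of the libraries.

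Of 11 tested genes within 200 kb of SLC2A3 on chromosome 12, 0 passed in limma and 0 had an unadjusted p under 0.05.

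The real division of the 6 libraries gave 418 called genes, 194 higher, 224 lower and 22 over 2-fold, and the highest count in the other 9 divisions was 0 for each by limma, with 952 to 1515 genes at an unadjusted p under 0.05 against 3293. For each of these, 1 of the 10 divisions reached the real count. For lists with the preset correlation, the real count of 16 was reached by 1 division and the highest other was 10. 10 divisions are too few for a share under 0.05. Each other division also mixes the groups, which lowers its gene counts wherever the groups differ, so these counts are no chance baseline.

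The histone list had a median of 0.57, with 4 of 16 members called, and passed with the preset correlation but not with an estimated correlation (adjusted p = 0.0863) or fry (0.0664). Its median was 0.36 without SLC2A3 overexpression replicate 2. More cells in S phase would raise DNA replication genes, but the median of that list was -0.12, which argues against this as the whole cause. More RNA without a poly(A) tail carried into the SLC2A3 libraries stays open. RN7SL1 was higher (3394 ± 2285 in the SLC2A3 group against 1018 ± 693). The median of 4 other such RNAs was 0.57 with 0 called and a camera p of 0.663. These had at most 22 normalised reads in any library, too few to decide, and SCARNA7 among them was lower (-1.02). RN7SL3, a gene of the RN7SL1 family left out of the 4, had a log2 change of 1.94 and did not pass (limma adjusted p = 0.0706). With RN7SL1 as a covariate the histone median fell to 0.27, past the threshold with the preset correlation (limma camera adjusted p = 0.036). An estimated correlation was not used there. That fit left 3 residual degrees of freedom, and RN7SL1 differs between the groups, so it does not decide the question.

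The ribosomal protein list, of short transcripts, had a median above 0 with 10 of 43 members called, and did not hold with an estimated correlation (adjusted p = 0.0863). The mitosis list had a median below 0 with 5 of 31 called, and held. A trend with transcript length and GC content was removed from each library to see whether these medians depend on it. The ribosomal protein median went from 0.111 to 0.084 and the mitosis median from -0.133 to -0.134. That most of each median remained argues against the trend as its whole cause. Both lists stayed past the preset-correlation test, which may overstate the evidence. An estimated correlation was not used after the removal, so that pass adds little for the ribosomal protein list. Culture conditions that differed between groups were not tested.

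The heat shock list was higher, with 6 of 15 members called. Without the near-identical HSPA1A and HSPA1B the median of the other 13 members was 0.13, with 4 called, and removing the length and GC trend left the list at 0.13, so neither accounts for the whole pattern. Handling stress of the SLC2A3 cultures cannot be told apart from an effect of SLC2A3, because the immediate early list, with a median of -0.051, did not pass (adjusted p = 0.0776) and culture is confounded with group. That list was lower past the preset-correlation threshold under 5 of 23 alternatives (lowest camera adjusted p = 0.0118). It did not pass with an estimated correlation (0.461) or fry (0.362). A lower list was set as going against handling stress only after the results were seen. Its members moved both ways, with JUN higher and FOS and EGR1 lower, so it does not decide the question.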
